A study of Mus musculus with 5 samples.

How the data were processed

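Gene expression was measured on Affymetrix arrays hybridised with biotin-labelled cRNA made from total RNA of mouse bone marrow mesenchymal stem cells (MSC) grown in primary culture. There were 5 arrays, each labelled as a separate biological repetition: 3 of MSC cultured alone and 2 of MSC cultured for 48 h in a transwell system with T cells activated through CD3 and CD28, at 10 T cells per MSC. The transwell membrane keeps the cell populations apart while soluble products pass. The groups were taken from the sample titles.

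The deposited values are log2 probe set summaries made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set. It gives no detection call, so no probe set could be called present or absent, and low values are compressed. The deposited table holds 3373 probe sets with values from 2.62 to 14.59, and not a whole array. In all 3373 of them both co-culture arrays lay above, or both lay below, every array of MSC alone, and the smallest difference between any co-culture array and any array of MSC alone was 0.34 on the log2 scale. The largest unadjusted p of an ordinary linear model, before any sharing of spread between probe sets, was 0.0583 (not an exact test). The table is therefore treated as selected on the comparison it is used for here. The rule of selection is not given in the sources used here. Genes outside the table were not analysed here, and nothing below says whether they changed.

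The probe table supplied with the platform's annotation gave 1 gene symbol for 3013 probe sets, several for 69 and listed no gene for 291. Entrez identifiers of 3010 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The named probe sets covered 2190 genes, 588 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean over the 5 arrays. Probe sets whose identifiers end in _s_at or _x_at can bind related transcripts, so values read from them (here those of Socs3, Gstm1, Rrm2, Prss23, Tpi1, H2-K1, H2-D1 and Mndal, and the other probe sets of Aspn and Psmb8) are uncertain, as are members of gene families of near-identical sequence such as the guanylate-binding proteins and the class I heavy chains. No column of the table was left unmatched to a sample.

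The test was limma (version 3.58.1 under R 4.3.3), with lmFit and eBayes on the deposited log2 values, all 5 arrays in 1 fit, no covariates and no filter, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run over the probe sets and again over the genes. Errors of log2 differences are limma's moderated standard errors (SE), and group values are means ± SD over arrays (n = 3 for MSC alone, n = 2 for co-culture). The number of arrays limits the precision. A selection for groups that do not overlap favours small spreads and large differences. The errors may therefore be too small and the differences too large. Where leaving out 1 array moved the fold of a gene named below by over 1.5 times, the value without that array is given. On simulated data for this comparison with 3373 probe sets, the fit recovered 2 of 50 probe sets changed by 0.5 on the log2 scale, 23 of 50 changed by 1, 47 of 50 changed by 2 and 50 of 50 changed by 3, with 4 false calls among 3173 unchanged probe sets. Most simulated probe sets were unchanged, unlike the selected table, and their spread was that fitted to the selected table. These counts therefore check the fit and do not give its recovery or false calls in the table itself. A second simulation drew 50000 unchanged probe sets with the fitted spread and kept those separated as in the deposited table: 1178 were kept, and 1131 of these (96.0%) passed the threshold when adjusted among themselves, against 0 when all were adjusted together.

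Where a range of adjusted p over alternatives is given, it covers those that keep the preset correlation. A total of 22 gene lists and 5 lists of markers of other cell types, the rule for named genes, the test and most alternatives were fixed before the data were examined. The rule for named genes takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with groups that do not overlap, up to 4 members of each list with the largest absolute difference, and 15 genes set in advance where measured. Genes that the results name outside this rule were chosen after their values were seen: Stat2, Irf7, Irf9, Cmpk2, Oas3, B2m, H2-K1, H2-D1, Nlrc5, Tgfb2, Fas, Ido1, Arg2, Cflar, Bcl2l1, Mdm2, Lamc1, Col6a2, Col12a1, Lox, Fn1, Plaur, Mki67, Cdt1, Ccne1, Pgk1, Tpi1, Tfrc and Pcx. For lists with at least 3 measured members, 18 in all, limma's camera compared the list with the other genes of the table, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 18 lists. Because the background is itself a selected table, camera asks only whether a list leans one way more than the other selected genes. Lists share some members, such as Cxcl11 and Cxcl9 (chemokines and interferon-gamma), Sod2 (NF-kB and NRF2) and Col1a1 and Sparc (matrix and osteogenic). They are not separate evidence. The camera test was repeated with an estimated correlation, and fry, which does not use other genes, was run as well. The mean level of each list per array was compared by an exact permutation test over the 10 splits of the arrays, which cannot give a p below 0.1. Alternatives were the replicate number as a block, leaving out each array in turn, 2 scalings, a filter on dim probe sets, other treatments of the spread, other thresholds and other rules for choosing a gene's probe set; 2 were added after the data were seen, one adjusting as if 15 times as many probe sets had been tested and one leaving out the shared kinds of probe set. No 2 arrays were the same throughout: exactly equal values occurred in at most 8 probe sets of any pair.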

Results

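The expression of mouse bone marrow MSC cultured alone was compared with that of MSC exposed for 48 h to activated T cells across a transwell membrane. MSC are stromal cells that support blood formation and can restrain T cell responses. The 5 arrays comprised 3 biological replicates of MSC alone and 2 of co-cultured MSC, and the deposited table held 3373 probe sets. Median log2 values over these probe sets were 7.64, 7.63 and 7.61 in MSC replicates 1, 2 and 3, and 7.50 and 7.42 in co-culture replicates 1 and 2. Across probe sets, Pearson's r was between 0.963 and 0.988 for pairs of MSC arrays, 0.966 for the co-culture arrays, and between 0.601 and 0.796 for pairs of different groups. Probe sets are not independent replicates, and the table was selected for separation of the groups, so the gap between these correlations is built in.

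Among the genes in the table, all 30 measured interferon-stimulated genes and all 13 of MHC class I and antigen processing were higher in co-cultured MSC than in MSC alone, and 30 of 31 extracellular matrix genes were lower. Of the 3373 probe sets, 1642 were higher and 1731 lower in co-culture, all with an adjusted p below the threshold in limma (largest adjusted p 0.0271). Differences of at least 2-fold were found in 926 higher and 1189 lower probe sets; with each array centred on its median the split turned to 1167 higher and 961 lower. Over the 2190 named genes, 1057 rose and 1133 fell. A call of every probe set is what the selection of the table produces: in simulation 96.0% of unchanged probe sets that met the same separation were called. Adjusted as if 15 times as many probe sets had been tested, a setting chosen after the data were seen, 205 higher and 210 lower probe sets passed. This setting changes only the number of tests. The spread still came from the selected probe sets, so these counts may be too high.

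Of the 10 genes with the largest rise, Cxcl11, Iigp1, Gbp3, Igtp, Cd274 and Gbp6 were members of the list of interferon-gamma-inducible genes, Tap1 of the MHC class I list and Zbp1 of the cell death list, and Ubd and Calhm6 of no list. Cxcl11, a chemokine ligand of CXCR3, rose by 6.67 ± 0.87 (SE) on the log2 scale, or 102-fold, from 6.49 ± 1.63 (SD, n = 3) to 13.17 ± 0.05 (SD, n = 2), with an adjusted p of 0.00301 in limma. Iigp1, an immunity-related GTPase, rose 90.4-fold from 4.65 ± 0.17 to 11.15 ± 0.47 (adjusted p 0.00015). Gbp3, a guanylate-binding protein, rose 51.5-fold, Igtp, another immunity-related GTPase, 42.7-fold, and Gbp6 39.5-fold. Ubd, a ubiquitin-like modifier also called FAT10, rose 50.1-fold. Cd274, which encodes the T cell inhibitory ligand PD-L1, rose 39.8-fold from 4.65 ± 0.28 to 9.96 ± 0.10 (adjusted p 0.00015). Zbp1, a sensor of Z-form nucleic acid, rose 38.1-fold, Calhm6 34.5-fold and Tap1, a subunit of the peptide transporter for class I loading, 31.9-fold. The size of a change depended on the probe set: the other probe sets of Cxcl11, Iigp1, Gbp6, Zbp1 and Tap1 rose by 3.60, 5.82, 3.80, 3.16 and 0.76 on the log2 scale. It also depended on single arrays. Without MSC replicate 3 the folds of Cxcl11, Gbp3 and Zbp1 were 53.2, 25.7 and 20.2. Without co-culture replicate 1 those of Ubd and Calhm6 were 77.2 and 54.9, and without co-culture replicate 2 they were 32.5 and 21.7. Ubd and Calhm6 had low means in MSC alone, 3.85 and 3.58, and Iigp1 and Cd274 also lay under 5 there. Without detection calls the folds of these genes are uncertain.

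**Figure D1:**
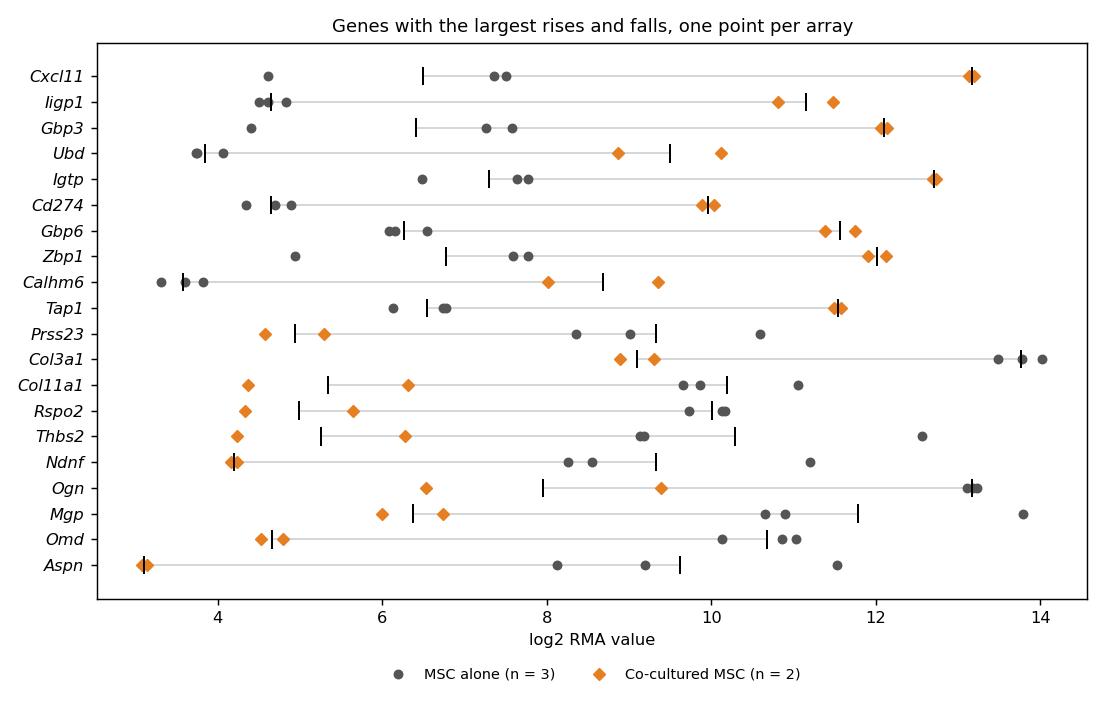
The horizontal axis is the log2 RMA value of the gene's probe set and each row is a gene; grey circles are the 3 arrays of MSC alone, orange diamonds the 2 co-culture arrays, and vertical ticks the group means. The upper 10 genes rose and the lower 10 fell; in Cxcl11, Gbp3 and Zbp1 MSC replicate 3 lay below the other MSC arrays, at 4.62 for Cxcl11 against 7.36 and 7.51.

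Of the 10 genes with the largest fall, Aspn, Ogn, Thbs2, Col11a1 and Col3a1 were members of the extracellular matrix list and Omd of the osteogenic list, and Mgp, Ndnf, Rspo2 and Prss23 of no list. Aspn, encoding the small leucine-rich proteoglycan asporin, fell by 6.51 ± 0.92 (SE) on the log2 scale, or 91.1-fold, from 9.62 ± 1.74 (SD, n = 3) to 3.11 ± 0.04 (SD, n = 2; adjusted p 0.00373 in limma). Omd, encoding osteomodulin, fell 64.7-fold from 10.68 ± 0.48 to 4.66 ± 0.19 (adjusted p 0.0002). Mgp, encoding matrix Gla protein, an inhibitor of calcification, was 42.7-fold lower. Ogn, encoding osteoglycin, was 37.1-fold lower, at 9.39 in co-culture replicate 1 and 6.53 in replicate 2 against 13.17 ± 0.06 in MSC alone. Ndnf was 35.1-fold, Thbs2, encoding thrombospondin-2, 32.9-fold, and Rspo2, a secreted enhancer of Wnt signalling, 32.5-fold lower. Col11a1 was 28.8-fold and Col3a1 25.5-fold lower, and Prss23, a serine protease gene, fell by 4.39 on the log2 scale. The other probe sets of Aspn and Col11a1 fell by 5.29 and 5.73. Aspn, at 3.11 in co-culture, lay near the lowest value of the table, 2.62. Omd, Ndnf, Rspo2 and Prss23 also had co-culture means under 5. Without detection calls the size of these falls is uncertain. MSC replicate 3 was the highest of the MSC arrays in several of these genes: without it Aspn was 47.0-fold, Mgp 21.3-fold, Ndnf 18.4-fold and Prss23 13.5-fold lower, and Thbs2 fell by 3.91 on the log2 scale. Without MSC replicate 2 Aspn was 153-fold lower. Without co-culture replicate 1 Ogn was 100.1-fold, Thbs2 66.9-fold, Col11a1 56.6-fold and Rspo2 51.2-fold lower, and without co-culture replicate 2 these were 13.8-fold, 16.2-fold, 14.7-fold and 20.6-fold lower. Without moderation of the spread the adjusted p of Thbs2 in limma's linear model was 0.0555, on the other side of the threshold; in the alternatives that keep the number of tests it lay between 0.00138 and that value.

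All 30 measured members of the list of genes induced by both type I and type II interferon rose, and so did all 16 measured interferon-gamma-inducible GTPases and regulators. The medians were 2.58 and 4.67 on the log2 scale. Ifit3 and Ifit2, antiviral proteins with tetratricopeptide repeats, rose by 4.96 ± 0.68 and 4.02 ± 0.30, Xaf1 by 3.56 ± 0.66 and Trim30a by 3.41 ± 0.64 (SE). Without MSC replicate 3 the rises of Ifit3, Xaf1 and Trim30a were 4.26, 2.87 and 4.09. The transcription factor genes Stat2, Irf7 and Irf9 rose by 2.62 ± 0.16, 2.85 ± 0.32 and 2.19 ± 0.21. The smallest rises of the first list were 0.86 ± 0.20 for Cmpk2 and 0.98 ± 0.20 for Oas3. The list test camera gave adjusted p = 1.38e-07 and 1.81e-06 (limma); with an estimated correlation both calls were lost (adjusted p = 0.361 for each). The mean level of the first list was 7.01, 7.09 and 6.28 in MSC replicates 1, 2 and 3, against 9.53 and 9.23 in the co-culture arrays, so MSC replicate 3 stood below the other controls. A total of 16 and 12 listed genes were not analysed here, and counts adjusted over the list alone were also 30 and 16.

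All 13 measured genes of MHC class I and antigen processing rose, with a median of 2.55 on the log2 scale. Of the 29 genes listed 16 were not analysed here. Besides Tap1, the immunoproteasome subunit genes Psmb9 and Psmb8 rose by 4.80 ± 0.29 and 4.16 ± 0.76 (SE), and Tapbpl, a peptide-exchange chaperone gene, by 3.35 ± 0.43. The light chain gene B2m, already at a high level, rose by 0.98 ± 0.16, and the heavy chain genes H2-K1 and H2-D1 by 1.93 ± 0.17 and 1.73 ± 0.16. Nlrc5, a transactivator of class I genes, rose by 3.03 ± 0.57. The rise of Psmb8 was 3.35 without MSC replicate 3, and that of Nlrc5 was 2.17 without co-culture replicate 1 and 3.89 without replicate 2. The other probe sets of Psmb8 and Tapbpl rose by 2.62 and 1.48. The list passed camera with adjusted p = 0.00017 (limma), and had adjusted p = 0.361 with an estimated correlation. Its mean level was also lowest in MSC replicate 3, at 7.78 against 8.51 and 8.61 in replicates 1 and 2, and 11.2 and 11.0 in the co-culture arrays. Psmb9 and Nlrc5 are also members of the interferon-gamma list. Of the 15 class II genes 1 was measured: Ctss, encoding cathepsin S, which rose by 2.89 ± 0.29 from a low mean of 3.36 in MSC alone.

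Ctss was also 1 of 2 measured genes of the 34 macrophage and monocyte markers. The other, Mpeg1, which encodes the pore-forming protein perforin-2, rose by 4.48 ± 0.25 (SE), from 4.64 ± 0.22 (SD, n = 3) to 9.12 ± 0.44 (SD, n = 2). Every gene in the table was selected to differ between the groups, so a shared rise does not tie them to the interferon and antigen processing genes. In MSC alone both were lowest in replicate 1 (4.40 for Mpeg1 and 3.08 for Ctss). The interferon-stimulated and class I lists were lowest in replicate 3. These are low values of the 2 genes without detection calls, so their order says little. In co-culture Mpeg1 was higher in replicate 1 than in replicate 2 (9.435 and 8.811), and so was Ctss (6.615 and 5.889). The means of both lists were also higher in co-culture replicate 1. The source of the 2 transcripts was not tested. Of 36 T cell, 17 B cell and granulocyte, 16 endothelial and 12 adipocyte and osteoclast markers 0 were in the table, so none of these cell types was analysed here.

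Of 8 measured chemokine genes 7 rose and 1 fell. Not analysed here were 23 of the 31 listed chemokines and 32 of 40 listed cytokines and growth factors. Ccl8 and Ccl7, monocyte-attracting chemokines, rose by 4.97 ± 0.24 and 3.68 ± 0.63 (SE), and Cxcl9 by 4.54 ± 0.73, although its other probe set rose by 0.82. Cxcl12, the stromal chemokine that retains blood progenitors in bone marrow, fell 11.5-fold, from 8.60 ± 0.99 (SD, n = 3) to 5.07 ± 0.15 (SD, n = 2; adjusted p 0.00425 in limma). Camera placed the list upward with adjusted p = 0.0263, a call lost with an estimated correlation (adjusted p = 0.388) and without the dimmest 25% of probe sets (adjusted p = 0.0562, the highest of the other alternatives, which reached down to 0.00867). The mean level of the chemokine list was lowest in MSC replicate 3, at 6.52 against 7.38 and 7.41 in replicates 1 and 2, and 9.69 and 9.99 in the co-culture arrays. Of 8 cytokine and growth factor genes 6 rose, led by Il15 (3.43 ± 0.45), Lif (3.08 ± 0.67) and Csf3 (2.27 ± 0.20), and Tgfb3 and Tgfb2 fell by 2.41 ± 0.34 and 2.09 ± 0.36; this list did not pass camera (adjusted p = 0.157). Without MSC replicate 3 the rises of Ccl7 and Lif were 3.03 and 2.43. Without co-culture replicate 1 those of Cxcl9 and Il15 were 5.90 and 4.19, and without co-culture replicate 2 they were 3.19 and 2.68.

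All 9 measured NF-kB targets and feedback regulators rose, with a median of 2.19 on the log2 scale. Not analysed here were 18 of the 27 listed NF-kB genes, 19 of 26 immunomodulatory genes and 16 of 27 cell death genes. Lcn2, encoding lipocalin-2, rose 20.6-fold from a low mean of 3.205 in MSC alone. Vcam1, an adhesion molecule for lymphocytes, rose 7.5-fold from 9.23 ± 0.17 (SD, n = 3) to 12.14 ± 0.10 (SD, n = 2). Nfkbiz and Sod2 rose 5.2-fold and 5.1-fold. All 7 measured genes of the list of immunomodulatory effectors of MSC rose: besides Cd274 and Lif (by 3.08, or 2.43 without MSC replicate 3), Nos2, encoding inducible nitric oxide synthase, rose 9.0-fold from 5.41 ± 0.22 to 8.58 ± 0.17, Socs3 by 1.95 ± 0.46, Fas by 1.87 ± 0.45, Ido1 by 1.00 ± 0.17 and Arg2 by 0.86 ± 0.21 on the log2 scale (SE). Without moderation of the spread Socs3 had an adjusted p of 0.0506 in limma's linear model, the highest of the alternatives that keep the number of tests, which reached down to 0.00157. Ido1 and Arg2 were low in all arrays, at 3.59 ± 0.14 and 3.51 ± 0.08 (SD, n = 3) in MSC alone. In co-culture they stood at 4.59 ± 0.04 and 4.37 ± 0.36 (SD, n = 2). Without a detection call, the size of their rises, and of the rise of Lcn2, is least certain. For the NF-kB and immunomodulatory lists camera gave adjusted p = 0.00069 and 0.00546 (limma), and adjusted p = 0.361 for each with an estimated correlation. Cd274, Nos2 and Ido1 are also members of the interferon-gamma list, Lif of the cytokine list and Fas of the cell death list. These lists are therefore not separate evidence. Of the 15 genes set in advance, Nos2, Cd274, Cxcl12, Vcam1 and Lif were measured; Timp1, Ptgs2, Il6, Ccl2, Ccl5, Icam1, Tnfaip6, Il1rn, Mmp2 and Mmp3 were not analysed here. Of 11 measured cell death and inflammasome genes 10 rose, among them Casp4 and Mlkl, which act in cell death, by 2.25 ± 0.17 and 1.98 ± 0.37. Genes that restrain death went both ways: Cflar, Bcl2l1 and Mdm2 rose by 1.81 ± 0.30, 1.35 ± 0.31 and 1.26 ± 0.31 (other probe sets of Cflar rose by 3.15 and 0.72), and Bcl2 fell by 2.01 ± 0.24 (its other probe sets fell by 1.74 and 0.95). This list had adjusted p = 0.0122 in camera, a call lost with an estimated correlation (adjusted p = 0.361) and without the dimmest 25% of probe sets (adjusted p = 0.0672, the highest of the other alternatives, which reached down to 0.0069).

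**Figure D2:**
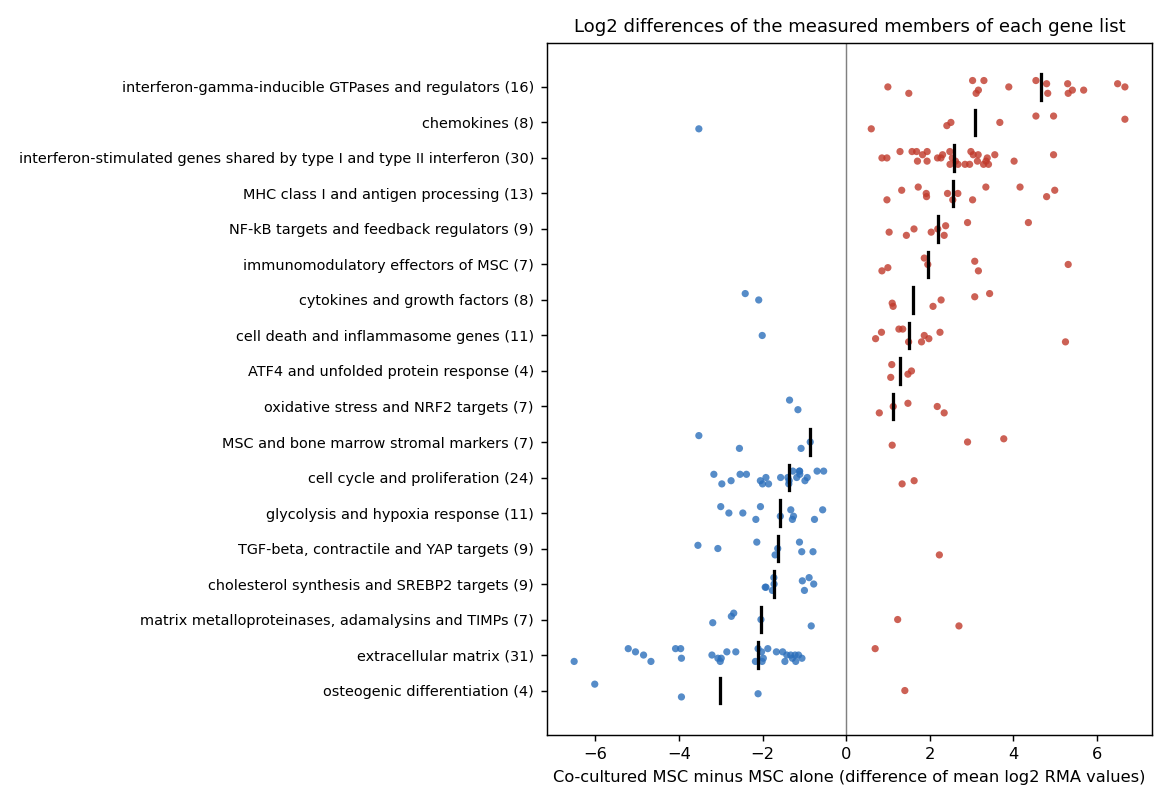
The horizontal axis is the difference of mean log2 values, co-cultured MSC minus MSC alone, and each row is a gene list with its number of measured genes in brackets; points are genes (red higher, blue lower) and black bars list medians. All 30 interferon-stimulated, 16 interferon-gamma-inducible and 13 class I genes lie above 0, and 30 of 31 matrix genes lie below it.

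Of 31 measured extracellular matrix genes 30 fell and 1, Lamc1, rose by 0.70 ± 0.18 (SE). The list median was -2.11 on the log2 scale. Of the 58 listed matrix genes 27 were not analysed here. Col1a1, encoding a chain of type I collagen, fell 15.4-fold from 13.16 ± 0.35 (SD, n = 3) to 9.21 ± 0.30 (SD, n = 2). Col6a2 fell by 4.08 ± 0.31 and Col12a1 fell by 3.96 ± 0.28 (SE). Lox, encoding an enzyme that cross-links collagen and elastin, fell by 1.98 ± 0.42, and Fn1, encoding fibronectin, fell by 1.21 ± 0.21. The size of a collagen's change depended on the probe set: Col3a1 fell by 4.67 in its brighter probe set and fell by 6.35 in its dimmer one, and Col1a1 fell by 3.94 in its brighter and fell by 5.13 in its dimmer one. In camera the matrix list had adjusted p = 6.34e-07 (limma), and adjusted p = 0.361 with an estimated correlation. Of 7 measured proteinase, adamalysin and inhibitor genes 5 fell, and 24 of the 31 listed were not analysed here. Mmp16 fell by 3.19 ± 0.47, Plat, encoding tissue plasminogen activator, fell by 2.75 ± 0.34 and Adamts5 fell by 2.69 ± 0.43. Plau, encoding urokinase, rose by 2.70 ± 0.32 and its receptor gene Plaur rose by 1.23. The other probe set of Plau rose by 1.75, and Adamts5 fell by 3.42 without co-culture replicate 1 and fell by 1.96 without replicate 2. The list did not pass camera (adjusted p = 0.294).

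Of 9 measured TGF-beta, contractile and YAP targets 8 fell, and 16 of the 25 listed were not analysed here. Myl9, a smooth muscle myosin light chain gene, fell by 3.55 ± 0.85 (SE), Thbs1 fell by 3.07 ± 0.48 and Inhba fell by 2.14 ± 0.29, and Skil, a feedback inhibitor of SMAD signalling, rose by 2.23 ± 0.32. Without MSC replicate 3 Myl9 fell by 2.66, and without MSC replicate 2 it fell by 4.17; Thbs1 fell by 3.92 without co-culture replicate 1 and fell by 2.22 without replicate 2. Without moderation of the spread Myl9 had an adjusted p of 0.0581 in limma's linear model, the highest of the alternatives that keep the number of tests, which reached down to 0.00116. The list's adjusted p = 0.0475 in camera lay close to the threshold; the call was lost with an estimated correlation (adjusted p = 0.361) and without MSC replicate 2 (adjusted p = 0.0502), and the other alternatives lay between 0.0355 and 0.0672. Among 7 measured MSC and marrow stromal markers 4 fell and 3 rose, and 17 of the 24 listed were not analysed here. The platelet-derived growth factor receptor genes went apart, Pdgfra rising by 3.77 ± 0.70 and Pdgfrb falling by 2.55 ± 0.44. Pdgfra rose by 3.08 without MSC replicate 3, and Pdgfrb fell by 3.19 without co-culture replicate 1 and fell by 1.92 without replicate 2. The median of this list was -0.86, its mean -0.03, and fry's direction was upward; neither camera (adjusted p = 0.887) nor fry (adjusted p = 0.127) passed. Of the 20 osteogenic genes 4 were measured: Omd, Col1a1 and Sparc fell and Msx2 rose by 1.41 ± 0.30, without a call for the list (adjusted p = 0.157). The 2 measured adipogenic genes, Cebpb and Cebpd, rose by 1.44 ± 0.34 and 2.19 ± 0.19, the 1 measured complement gene, Cfb, rose by 1.31 ± 0.27, and 0 of 12 chondrogenic genes were in the table. Cebpb and Cebpd are also members of the NF-kB list and are not separate evidence. Not analysed here were 18 of the 20 listed adipogenic and 19 of the 20 listed complement genes.

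Of 24 measured cell cycle genes 22 fell, and 38 of the 62 listed were not analysed here. Rrm2, a ribonucleotide reductase subunit gene, fell by 3.17 ± 0.40 (SE), the kinetochore genes Nuf2 and Cenpf fell by 2.97 ± 0.36 and 2.54 ± 0.24, the cyclin gene Ccna2 fell by 2.75 ± 0.39 and the proliferation marker Mki67 fell by 2.39 ± 0.33. The other probe sets of Rrm2 fell by 2.01 and 3.32. Cdt1, a replication licensing factor, and Ccne1, encoding cyclin E1, rose by 1.63 ± 0.33 and 1.34 ± 0.33. The cell cycle list had adjusted p = 0.00045 in camera (limma), and adjusted p = 0.388 with an estimated correlation.

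All 11 measured glycolysis and hypoxia response genes and all 9 measured cholesterol synthesis and SREBP2 target genes fell. Not analysed here were 17 of 28 listed glycolysis and hypoxia, 14 of 23 cholesterol, 19 of 26 NRF2 and 25 of 29 ATF4 genes. In the first list Egln1, an oxygen-sensing prolyl hydroxylase gene, fell by 3.00 ± 0.30 (SE), Car9 fell by 2.81 ± 0.28, Pdk1 fell by 2.47 ± 0.37 and Bnip3 fell by 2.16 ± 0.46 (the other probe set of Egln1 fell by 2.11), while the abundant enzyme genes Pgk1 and Tpi1 fell by 0.56 ± 0.16 and 0.76 ± 0.19. In the second, Stard4, Lss, Cyp51 and Idi1 fell by 1.94 ± 0.27, 1.92 ± 0.36, 1.76 ± 0.36 and 1.73 ± 0.35. Their adjusted p values in camera were 0.00165 and 0.00955 (limma), with adjusted p = 0.388 for each with an estimated correlation. Of 7 measured oxidative stress and NRF2 targets 5 rose, led by Sod2 and by the glutathione synthesis gene Gclm (2.18 ± 0.21), and Gstm1 fell by 1.35 ± 0.16 (its other probe sets fell by 1.30 and 0.74); the list did not pass (adjusted p = 0.220). All 4 measured ATF4 and unfolded protein response genes rose, Sdf2l1 by 1.56 ± 0.35, the cystine transporter gene Slc7a11 by 1.48 ± 0.31, Slc3a2 by 1.09 ± 0.27 and Creld2 by 1.07 ± 0.26; the list had adjusted p = 0.0779 in camera, and 0.0355 without MSC replicate 3, with alternatives up to 0.145.

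The counts of each list adjusted over the list alone equal those adjusted over all genes by construction, because the unadjusted p of every gene was below the threshold. For the mean level per array, 17 of the 18 lists gave an exact permutation p of 0.1 (two-sided), the smallest that 10 splits allow, and the stromal markers gave 0.7. The selection of the table fixes this outcome for any list whose members all moved one way, so the test adds nothing to the counts of direction. In limma's fry, which asks whether a list's genes move one way on balance without a comparison with other genes, 17 of the 18 lists passed. Among these were 5 that did not pass camera: cytokines (fry adjusted p = 0.00477), proteinases and inhibitors (0.00315), osteogenic genes (0.00423), ATF4 and unfolded protein response genes (0.0217) and NRF2 targets (0.0086). Genes in this table were selected for a difference, which favours a pass in fry. No list passed camera with an estimated correlation. The estimates, made with 3 residual degrees of freedom, included correlations of 0.367 for interferon-stimulated, 0.0892 for interferon-gamma-inducible, 0.129 for extracellular matrix, 0.335 for cell cycle and 0.707 for glycolysis and hypoxia genes. The TGF-beta, contractile and YAP list had an estimate of -0.0184, below the preset value, and still lost its call (unadjusted p = 0.0317 with the preset correlation and 0.112 with the estimate), so correlation between members did not end that call. For the other lists low power and correlation were not separated. Control-named probe sets for transferrin receptor (Tfrc) rose by 0.83 at the 3' end and 0.70 in the middle of the transcript, and those for pyruvate carboxylase (Pcx) fell by 0.84 and 0.77; control probe sets outside the table were not analysed here.

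**Figure D3:**
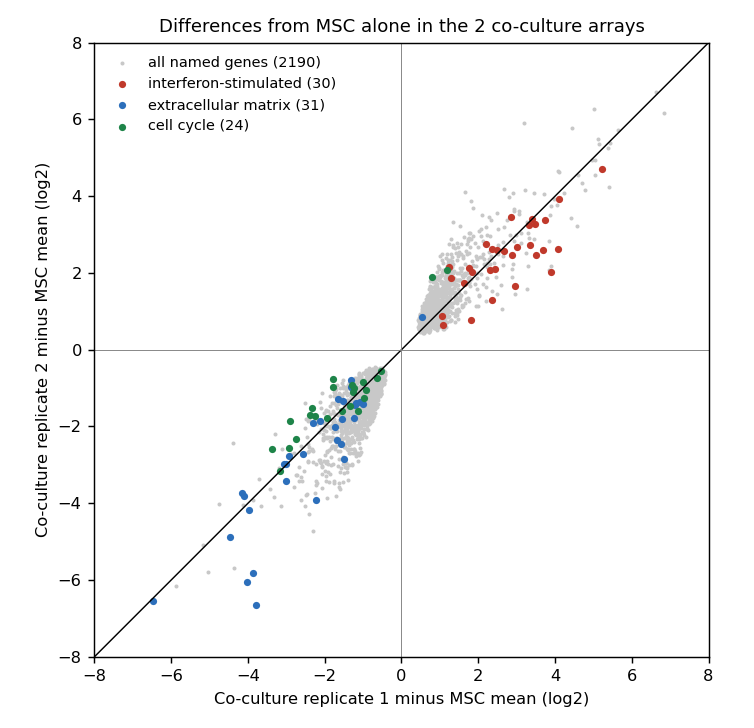
Each point is a named gene, with its difference from the mean of MSC alone (log2) in co-culture replicate 1 on the horizontal axis and in replicate 2 on the vertical axis; the diagonal marks equal differences, red points are interferon-stimulated, blue extracellular matrix and green cell cycle genes. The empty band around 0 is the selection of the table; 78.2% of genes that fell and 69.0% of those that rose lay farther from MSC alone in replicate 2.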

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

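Of the alternatives, the adjustment for 15 times as many tests and the omission of shared kinds of probe set were chosen after the data were seen. Adjusted as if 15 times as many probe sets had been tested, 205 higher and 210 lower probe sets passed, the same numbers with the 2-fold limit, and the members that passed fell to 11 interferon-stimulated, 10 interferon-gamma-inducible, 5 MHC class I, 10 extracellular matrix, 5 cell cycle, 3 glycolysis and hypoxia and 0 cholesterol genes; 42 of the 80 named genes were lost. With a limit of 1.5-fold in place of 2-fold, 1572 probe sets were higher and 1686 lower. With the replicate number as a block, 1636 higher and 1729 lower probe sets passed, and the ATF4 list was called (adjusted p = 0.0396, limma); the block changed no other call of a list or a named gene. The deviations of same-numbered arrays from their group means correlated with r = 0.22 for number 1 and r = 0.32 for number 2 across probe sets, but with only 2 pairs this does not decide whether a number marks a shared culture or day, and the samples were not treated as paired. Leaving out each array in turn left between 1497 and 1641 higher and between 1619 and 1730 lower probe sets past the threshold; the selection of the table favours such retention and fixes the signs. Where a group was left with 1 array, it was assumed to vary like the other. The median difference was -0.58 as deposited, -0.42 with arrays centred on their medians and -0.35 after quantile normalization. As deposited, no difference of means was smaller than 0.467 in absolute size. The median therefore follows the counts of rises and falls and does not measure a typical change. The share of calls that were higher was 48.7% as deposited, 49.5% centred and 49.8% after quantile normalization. The call of the TGF-beta, contractile and YAP list was lost under 6 settings (adjusted p from 0.0502 to 0.361), those of chemokine and cell death genes under 2 each, and all 12 camera calls with an estimated correlation. The balance of probe sets changed by at least 2-fold turned from 926 higher and 1189 lower to 1167 higher and 961 lower with centring. Centring raised every difference by 0.164, because the co-culture arrays had lower medians over this table. These medians come from probe sets selected to differ, so this balance depends on the scaling. Low values lack detection calls: 295 probe sets had a mean under 5, where the size of a change is least certain.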

Other observations

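The genes in this paragraph, the test of symbol stems and the test of a stronger response in every gene group were chosen after their values were seen. Slc7a2, an arginine transporter gene, rose by 2.20 ± 0.52 (SE) and Gch1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, by 2.08 ± 0.50 on the log2 scale. The interleukin-15 receptor gene Il15ra rose by 2.15 ± 0.35 beside Il15, and Il18bp, a secreted antagonist of interleukin-18, by 2.39 ± 0.34. The interferon-inducible Ifi200 family members Ifi207, Mndal and Ifi213 rose by 4.58 ± 0.17, 3.92 ± 0.17 and 2.83 ± 0.24. Slpi, a secreted protease inhibitor, rose by 3.50 ± 0.50, Hcar2, a hydroxycarboxylic acid receptor gene, by 4.36 ± 0.31 and Ptgir, the prostacyclin receptor gene, by 3.16 ± 0.26. Elovl6, Scd2 and Acss2, which encode enzymes of lipid synthesis, fell by 2.64 ± 0.43, 2.46 ± 0.33 and 2.56 ± 0.27. Irs1, an adaptor of insulin signalling, fell by 4.08 ± 0.35, and Ccn4 and Tmem119 fell by 2.99 ± 0.47 and 3.87 ± 0.39. Without co-culture replicate 1 Gch1 and Slpi rose by 2.68 and 4.09, and Elovl6 and Ccn4 fell by 3.29 and 3.72. Without co-culture replicate 2 Gch1 and Slpi rose by 1.48 and 2.91, and Elovl6 and Ccn4 fell by 1.98 and 2.25.

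Among 33 symbol stems with at least 6 genes, collagens alone leaned one way past the threshold: 13 of 13 fell, with a median of -3.01 (two-sided Fisher's exact test against all other genes, adjusted p = 0.00852). Most of these collagens are also members of the extracellular matrix list, so their fall is not separate evidence. Genes of mitochondrial ribosomal proteins (Mrpl) and RNA-binding motif proteins (Rbm) rose in 7 of 8 cases each. Protocadherin beta genes (Pcdhb) fell in 6 of 6. None of the Mrpl, Rbm and Pcdhb stems passed (exact test, adjusted p = 0.273 for each). The Fisher test treats genes as independent.

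Co-culture replicate 2 lay farther from MSC alone than replicate 1, by a median ratio of 1.21 (95% bootstrap interval over genes 1.18 to 1.23) in genes that rose and 1.33 (1.30 to 1.35) in genes that fell. The ratios differ by 0.118, which argues against a single factor on all differences from MSC alone as the whole cause. A stretch of the array about its own level, with an offset, was not tested. Replicate 2 had an SD over probe sets of 2.24 and a median of 7.42, against 2.12 and 7.50 in replicate 1. Interferon-stimulated genes went the other way, with a median ratio of 0.902 (0.840 to 0.991) and 20 of 30 genes nearer to MSC alone in replicate 2. Cell cycle genes, most of which fell, had a ratio of 0.876 (0.782 to 1.04) and class I genes 0.958 (0.899 to 1.04). NF-kB targets and extracellular matrix genes lay above 1, at 1.13 each. In these arrays the larger difference was not shared by every gene group. The intervals treat genes as independent. Interferon-stimulated genes had an estimated correlation of 0.367, so their interval is too narrow to decide against a uniformly stronger response. Among all rising genes the median ratio was 1.21, and in other rising genes matched on level and change in replicate 1 it was 1.01. Level and size of change thus go with part of the gap. The interferon-stimulated genes lay lower than their matched genes by -0.173 (-0.241 to -0.083), which argues against a ceiling as the whole cause. This interval also treats genes as independent. A candidate explanation that stays open is that the replicates differed in the balance of soluble signals or in timing; with 1 array on each side no biological explanation was tested.

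Interferon-stimulated genes were lowest in MSC replicate 3: 28 of 30 lay below the mean of replicates 1 and 2, with a median deviation of -0.565 (95% bootstrap interval over genes -0.970 to -0.329). Other rising genes of similar level deviated by -0.074, and the interferon-stimulated genes lay lower than these by -0.454 (-0.869 to -0.289), which argues against a shift of all rising genes in that array. The 15 genes with a mean of 7 or more in replicates 1 and 2 all lay below it, by a median of -1.16 (-2.12 to -0.640), which argues against noise of dim probe sets. MSC replicate 3 also stood apart from replicates 1 and 2 in the mean level of other lists: 6.52 against 7.38 and 7.41 for chemokines, 6.58 against 7.19 and 7.26 for cell death, 11.79 against 12.27 and 12.35 for glycolysis and hypoxia, and 7.93 against 7.51 and 7.47 for cell cycle genes. The bootstrap intervals treat genes as independent, although the interferon-stimulated genes had an estimated correlation of 0.367, and they rest on a single array. The cause stays open, and no biological explanation was tested.

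Whether a gene's brighter probe set moves less than its dimmer one is not decided by this table: probe sets that moved little are missing by its selection, and the genes compared were those whose probe sets agreed in direction. The brighter one moved less in 49.6% of 548 such genes (exact binomial test, p = 0.898). It did so in 124 of 216 genes whose brightest probe set was among the brightest 25% (exact binomial test, p = 0.0347, unadjusted among 5 tests), where the median difference was -0.056, and in 44.6% of genes with all probe sets below that range (same test, p = 0.0546, difference 0.0632, 0.001 to 0.138). Rising genes gave 55.6% (exact binomial test, p = 0.0805, difference -0.031) and falling genes 44.3% (exact binomial test, p = 0.0605, difference 0.051), so compression near the top of the range and a chance order of the probe sets both stay open. In 40 of 588 genes with several probe sets the probe sets moved in opposite directions, for example Rala, whose brighter probe set rose by 0.70 and whose dimmer one fell by 2.35.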
